A study of Nannochloropsis oceanica with 6 samples.

How the data were processed

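RNA-seq tables of 6 libraries of Nannochloropsis oceanica IMET1 were used, 3 from cultures at 5% CO2 (high CO2) and 3 from cultures at 0.04% CO2 (low CO2). Per the labels' protocols, equal numbers of seed cells went into 6 reactors of 800 ml of f/2-type medium with 10 mM Tris at pH 8.2, at an OD750 of 1.5. RNA was extracted with Trizol, and poly(A) libraries were made by Illumina protocols. Groups and replicate numbers came from the submitters' titles.

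Per the submitters' processing notes, Trim Galore, STAR, Picard, featureCounts, StringTie and edgeR were used, with no versions, roles or order stated. The genome build and annotation were not given in the sources used here, and gene positions were not used. Per the file headers, each deposited per-library table held an expected count, a TPM and an FPKM value per gene, with a gene length and descriptions. The expected counts deposited by the authors were not normalized, and 17.5% to 19.8% of the values in a library differed from a whole number by more than 0.004. The TPM values deposited by the authors summed to 1000000 per library. The FPKM values deposited by the authors are scaled by gene length and library size, and they were used to describe levels, with SD over 3 replicates. Of 10633 genes, 10333 had a locus number and 300 had other identifiers. The gene table of the reference held 160 genes, of which 0 matched an identifier, so names were taken from the descriptions in the deposited tables. A further table by the authors gave their own log2 fold change, p-value and adjusted p-value for 217 genes; its 1302 FPKM values all equalled the per-library tables within 0.005. Its log2 fold changes had the sign of low over high CO2 mean FPKM in 216 of the 217 genes.

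The design written before the data were examined foresaw whole-number counts or FPKM alone. The tables held expected counts, so these were rounded to whole numbers and given the test foreseen for counts. Genes passed edgeR's filterByExpr (9244 of 10633), libraries were scaled by TMM, and the 2 groups were compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, without a replicate block. Fold changes are coded low minus high CO2, standard errors are the log2 fold change divided by the root of the F statistic, and a call is a Benjamini-Hochberg adjusted p below 0.05. The biological coefficient of variation was 23.1%. The test was checked on simulated counts with 200 changed genes among 9244: it recovered 9%, 50.7% and 98.5% of changes of 1.5-fold, 2-fold and 4-fold, and 4.5% of its calls were unchanged genes. The camera test ranked a list simulated with a log2 shift of 0.5 at rank 1, and called 0 of the other lists. Genes were simulated independently of each other, so this check says nothing about false calls of lists whose genes move together. Spread was simulated from its fitted trend on expression, and no simulated library stood apart from its group, unlike in the data. Recovery and the share of unchanged genes among calls may thus differ in the data.

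In all, 25 gene lists were fixed as word patterns on the descriptions, and 24 had members; the list of organelle genes and ribosomal RNA had none. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 24 lists. Of 848 genes in any list, 19 were in more than 1. Patterns take in some genes that share a word and not a function, and these are named where they matter.

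Genes named in the text followed a rule set beforehand. It took the 6 largest rises and 6 largest falls among called, described genes with a mean of at least 5 FPKM and no overlap between groups. It also took all called members of the carbonic anhydrase and bicarbonate lists, up to 2 called members of each other list with calls, and 2 rises and 2 falls without a description, which came to 27 genes. For a gene at 0 in a whole group, the fold is a lower bound against 3 counts over that group's summed total. With 1 to 3 counts, the ratio of shares has an exact 95% interval. Reads carry no molecular identifiers, so these cover counting error only. Totals per library were 4620234 to 6112822 counts, and spread between replicates is not covered.

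Alternatives planned beforehand were a replicate block, no filter, a mean of at least 50 counts, RLE scaling, a 2-fold minimum, DESeq2 1.42.0, limma on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, and leaving out each library. For lists, they were an estimated correlation, fry, the block, filters, scaling and leaving out each library. Alternatives meant for an FPKM-only design were not run, since counts were given. After seeing the data, 3 were added: leaving out both libraries that stood apart, removing a smooth trend on gene length from each library, and leaving out 6, 6 and 3 genes of the desaturase, Calvin cycle and C4-type lists whose descriptions name another function. Closing tests and figures used Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9. Organelle transcripts were not analysed here.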

Results

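Transcript levels were measured in Nannochloropsis oceanica strain IMET1, a small marine alga of the eustigmatophytes that is grown for its oil, in cells kept under high CO2 or moved to low CO2. Poly(A) RNA was sequenced from 6 separate column reactors, 3 per group, so the replicates were separate cultures. The 3 high CO2 cultures (the control) stayed on air with 5% CO2, and the other 3 were switched to air with 0.04% CO2 after 1 h of adaptation at 5%. All were sampled 24 h later, at 80 µmol photons m-2 s-1 and 25 °C. The deposited tables gave estimated counts for 10633 genes. The high CO2 replicates 1, 2 and 3 held 5140784, 5079605 and 4826380 counts, and the low CO2 replicates 1, 2 and 3 held 4620234, 5607726 and 6112822. The most abundant gene was NO25G00860, an antenna protein, with 1.62% to 2.11% of the counts of a library, and 724 to 883 genes were at 0 in a library.

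The libraries of each group were first compared with each other. High CO2 replicates 1 and 2 were close (Pearson's r of log2 CPM, counts scaled to library size, across 9244 genes 0.982, where genes are not independent replicates), as were low CO2 replicates 2 and 3 (r = 0.987). High CO2 replicate 3 and low CO2 replicate 1 stood apart from the rest of their groups. High CO2 replicate 3 differed from replicate 1 by more than 2-fold at 821 genes, against 192 genes between replicates 1 and 2. Low CO2 replicate 1 differed from replicate 2 by more than 2-fold at 1154 genes, against 96 genes between replicates 2 and 3, and its r with the high CO2 replicates 1 and 2 (0.942 and 0.946) was above its r with the low CO2 replicates 2 and 3 (0.924 and 0.932).

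**Figure D1:**
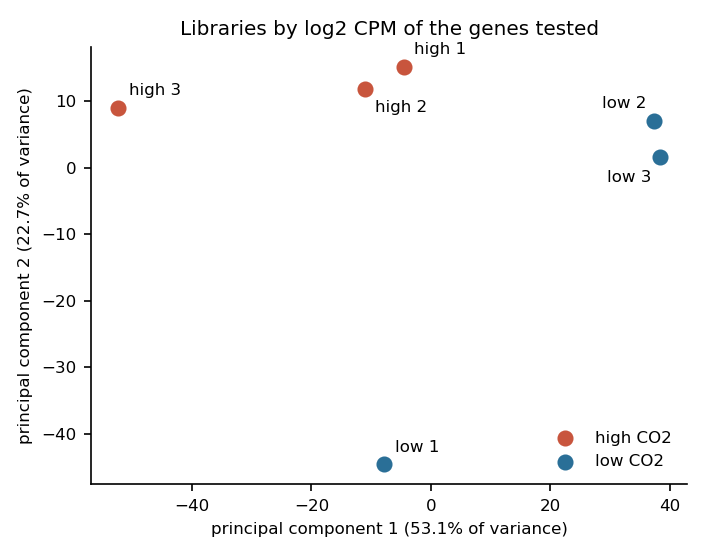
Principal components 1 (53.1% of the variance) and 2 (22.7%) of log2 CPM, in arbitrary units, with 1 point per library coloured by group. High CO2 replicate 3 lies at -52.38 on component 1, and the other 2 high CO2 libraries at -4.56 and -11.11. Low CO2 replicate 1 lies between those 2 on component 1, at -7.78, while low CO2 replicates 2 and 3 lie at 37.44 and 38.38. On component 2, low CO2 replicate 1 lies alone at -44.55.

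Differences of these libraries from the rest of their groups followed gene length in part. Spearman's correlation with length was -0.26 for high CO2 replicate 3 and -0.21 for low CO2 replicate 1. In the shortest of 8 equal bins of genes (201 to 901 bases), the median log2 difference of high CO2 replicate 3 from replicates 1 and 2 was 0.26, and that of low CO2 replicate 1 from replicates 2 and 3 was 0.22. In the longest bin (3671 to 48853 bases) these medians were -0.13 and -0.20. The fold change between groups ran the other way, from a median log2 of -0.16 in the shortest bin to 0.13 in the longest.

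**Figure D2:**
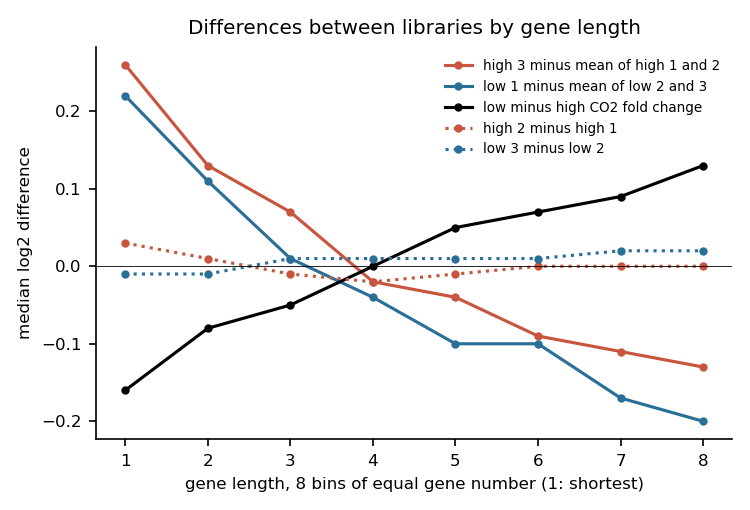
Median log2 difference (vertical axis) in 8 bins of equal gene number ordered by gene length (horizontal axis, shortest first), for 4 comparisons within groups and for the low minus high CO2 fold change. The lines of high CO2 replicate 3 and low CO2 replicate 1 fall from 0.26 and 0.22 to -0.13 and -0.20, while the dotted lines of the other replicates stay between -0.02 and 0.03.

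The main comparison asked which transcripts differed between cells at 0.04% and at 5% CO2. Phototropin-1B (NO01G04880), annotated as a blue-light receptor kinase, rose 7.05-fold in low CO2, from 18.6 ± 2.97 to 137 ± 9.76 FPKM (SD, n = 3 per group). A ferredoxin (NO09G00110), a small iron-sulfur electron carrier, fell from 1113 ± 116 to 147 ± 16.9 FPKM, and was thus 7.98-fold higher in high CO2. A pair of genes annotated as heat shock protein 16, small heat shock proteins, fell: NO20G02130 from 1296 ± 35.3 to 415 ± 32.9 FPKM and NO20G02150 from 731 ± 75.2 to 240 ± 20.7 FPKM. A glutaredoxin arsenate reductase (NO20G00140) fell from 130 ± 7.74 to 36.8 ± 8.76 FPKM, and a 31 kDa chloroplast ribonucleoprotein (NO15G00910) rose from 0.453 ± 0.212 to 13.2 ± 3.18 FPKM. The log2 fold changes (low minus high CO2) were 2.82 (SE 0.14, adjusted p = 0.000308) for the phototropin, -3.00 (SE 0.14, adjusted p = 0.000308) for the ferredoxin, -1.82 (SE 0.11, adjusted p = 0.00059) and -1.66 (SE 0.12, adjusted p = 0.00104) for the heat shock proteins. They were -1.74 (SE 0.24, adjusted p = 0.0173) for the reductase and 4.50 (SE 0.45, adjusted p = 0.00531) for the ribonucleoprotein, in edgeR's quasi-likelihood test. Among the genes without a description, NO26G01620 rose 7.87-fold (adjusted p = 0.0432) and NO04G01800 6.60-fold (adjusted p = 0.00135).

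**Figure D3:**
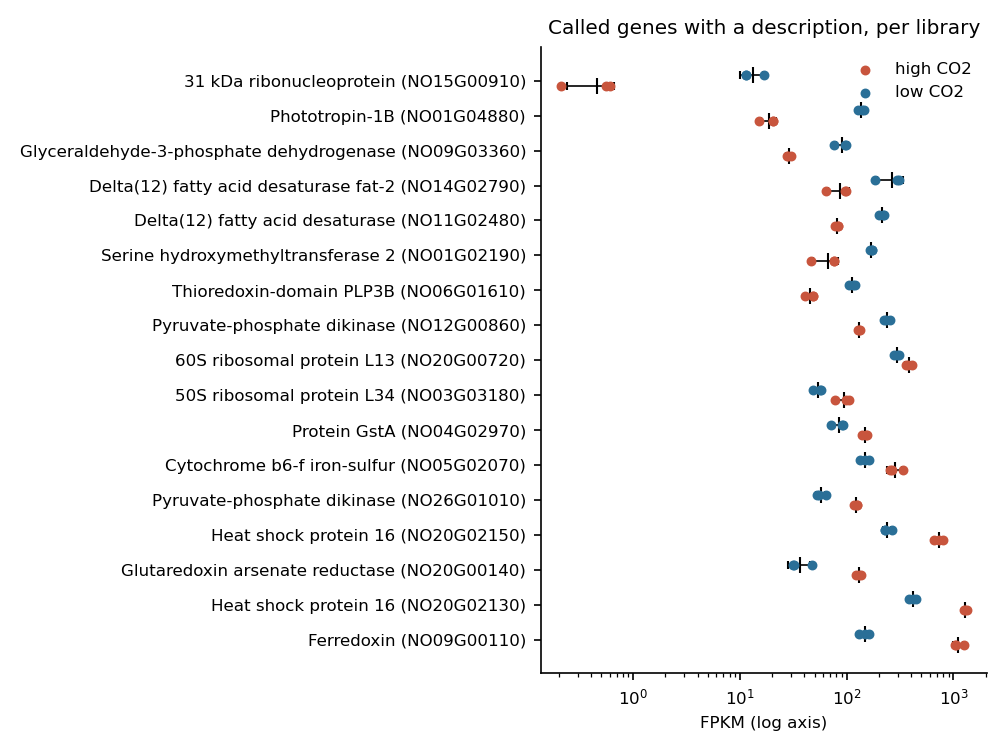
FPKM (horizontal log axis) of the described genes chosen by the naming rule whose 6 libraries were all above 0, with 1 point per library and the group mean and SD in black. The 3 low CO2 points of phototropin-1B lie to the right of its high CO2 points (137 against 18.6 FPKM on average), and those of the ferredoxin to the left (147 against 1113 FPKM).

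Across the 9244 genes tested, 113 rose and 83 fell in low CO2 (196 in all; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 71 of those that rose and 38 of those that fell changed at least 2-fold. The FPKM values of the groups did not overlap at any of the 196 genes; among all genes tested this held for 25.4%, where chance gives 10%. A description was given for 123 of the 196 genes, and 73 had none. The count varied with the library left out: it was 35, 18 and 68 without high CO2 replicates 1, 2 and 3, 1610, 48 and 50 without low CO2 replicates 1, 2 and 3, and 3402 without both libraries that stood apart, a choice made after seeing the data. DESeq2's Wald test called 590 genes. Of the 27 genes chosen by the naming rule, the phototropin, the ferredoxin, both heat shock proteins, the glyceraldehyde-3-phosphate dehydrogenase NO09G03360 and NO04G01800 passed under every alternative run (6 genes). Of the 27, 10, 8 and 12 passed without high CO2 replicates 1, 2 and 3, and 27, 11 and 12 without low CO2 replicates 1, 2 and 3.

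Several of the largest changes were at gene models with no counts at all in 1 group. Models annotated as phosphoribulokinase (NO13G02830), the Calvin cycle kinase that makes ribulose bisphosphate, as pyruvate kinase (NO06G01630) and as the deoxyribonuclease TATDN1 (NO02G00710) were at 0 in all 3 high CO2 libraries. Against a floor of 3 counts over the high CO2 group they were at least 687-fold, 570-fold and 51.6-fold higher in low CO2 (adjusted p = 0.0182, 0.0349 and 0.0205 in edgeR). A peptide chain release factor subunit, ERF3A (NO14G02430), had 2 counts in the high CO2 group and 70 to 189 in each low CO2 library, a ratio of 186 (95% counting interval 51.0 to 1537; adjusted p = 0.00409). Models at 0 in all 3 low CO2 libraries were annotated after a bacterial NADH dehydrogenase gene, nox (NO09G03180), and as the ubiquinone synthesis enzyme 4-hydroxybenzoate polyprenyltransferase (NO14G01380), with NO17G01030 and NO16G02930 undescribed. They were at least 178-fold, 39.5-fold, 144-fold and 35.5-fold lower in low CO2 (adjusted p = 0.0125, 0.0407, 0.0407 and 0.0349). For 4 of these models, the neighbouring locus number carries the same description and a longer gene. The longer phosphoribulokinase (NO13G02820) had a log2 fold change of -0.21 (SE 0.17, adjusted p = 0.537), the longer pyruvate kinase (NO06G01620) one of 0.42 (SE 0.10, adjusted p = 0.0796), the longer TATDN1 gene (NO02G00700) one of 0.38 (SE 0.14, adjusted p = 0.203) and the longer polyprenyltransferase (NO14G01370) one of 0.27 (SE 0.11, adjusted p = 0.252). The summed phosphoribulokinase pair was 1432 ± 154 CPM in high and 1359 ± 215 in low CO2. The summed pyruvate kinase pair was at 865 ± 25.8 and 1260 ± 40.3 CPM, the summed TATDN1 pair at 59.3 ± 5.08 and 87.5 ± 10.2, and the summed polyprenyltransferase pair at 113 ± 9.51 and 127 ± 1.67, with n = 3 each. Counting between such neighbours is uncertain, and floors and intervals cover counting error only.

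Genes of inorganic carbon uptake were examined as lists fixed before the data were examined. Of 5 carbonic anhydrases, which interconvert CO2 and bicarbonate, none passed over all genes, and 1 was higher and 1 lower when adjusted over the list alone. Their log2 fold changes ran from -0.42 (NO04G04510, a mitochondrial gamma type, 612 to 484 FPKM) to 0.70 (NO01G01240, 42.0 to 70.5 FPKM), and the list had a camera adjusted p of 0.758. None of 4 genes on the list of bicarbonate and anion transporters passed, also adjusted over the list alone (camera adjusted p = 0.626). That list took in the band 3 anion transport protein NO01G02900 and the sodium bicarbonate exchanger NO08G01230, and by their wording also an iron exporter-like gene and an aldose reductase. Simulated counts had this depth, 3 libraries per group and the fitted trend of spread on expression, but no library that stood apart. Over 9244 genes, the test recovered 9% of 1.5-fold, 50.7% of 2-fold and 98.5% of 4-fold changes. Most changes of 1.5-fold were thus missed even in such counts, and recovery in these lists may differ.

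Of 37 genes on the Calvin cycle list, 2 rose, none fell and 35 did not pass (5 higher and 1 lower adjusted over the list alone). By their wording, 6 of the 35 are on the list without being enzymes of the cycle: the methyltransferases NO10G04020, NO16G02450, NO02G01160, NO16G00490 and NO10G01300, and the arabinolactonase NO16G03210. The pattern asks for enzyme names and not for a compartment, so the other members need not all act in the cycle. Besides the phosphoribulokinase model at 0, a glyceraldehyde-3-phosphate dehydrogenase (NO09G03360) rose 3.02-fold, from 28.5 ± 1.26 to 90.8 ± 12.3 FPKM (adjusted p = 0.00104). Its name gives no compartment. Among 19 genes on the list of C4-type carboxylation and decarboxylation enzymes, which by their wording took in 2 protein kinases and an isopropylmalate dehydrogenase, the 2 that passed are both annotated as pyruvate, phosphate dikinase, which makes phosphoenolpyruvate from pyruvate. NO12G00860 rose from 131 ± 3.47 to 237 ± 16 FPKM (adjusted p = 0.031) and NO26G01010 fell from 122 ± 5.33 to 57.0 ± 5.73 FPKM (adjusted p = 0.0142). Adjusted over the list alone, 3 of the 19 were higher and 2 lower, and the list's median of -0.01 and mean of 0.13 differed in sign. Of 20 photorespiration genes, serine hydroxymethyltransferase 2 (NO01G02190), which links glycine, serine and folate, rose 2.47-fold, from 66.2 ± 17.4 to 170 ± 4.60 FPKM (adjusted p = 0.0205), and 19 did not pass (3 higher and 2 lower adjusted over the list alone). None of the 6 glyoxylate cycle genes passed (1 lower adjusted over the list alone). No call was made by camera for these 4 lists (adjusted p = 0.0766, 0.774, 0.241 and 0.428). For the Calvin cycle list it was 0.216 without the phosphoribulokinase model at 0 and 0.438 with an estimated correlation, both with all libraries. The alternatives that follow kept that model and were not run without it. The list was called as higher in low CO2 without high CO2 replicate 3, low CO2 replicate 2 or low CO2 replicate 3 (0.0405, 0.0484 and 0.0307), with a mean of at least 50 counts (0.0427), by fry (0.0158), which asks whether a list's genes move 1 way on balance without comparing them with other genes, and without the 6 genes of another function (0.0358, but 0.438 with an estimated correlation), a choice made after seeing the data.

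The list of fatty acid desaturases and elongases, which add double bonds or carbons to acyl chains, had the highest median of the 24. By their wording, 6 of its 29 members act on carotenoids or sterols: the carotene and phytoene enzymes NO03G05250, NO27G00040, NO14G02800 and NO16G01970, and the sterol enzymes NO03G03660 and NO23G01090, none of which passed. Of the 29, 5 rose, none fell and 24 did not pass (7 higher adjusted over the list alone), with a median log2 fold change of 0.31. All 5 are annotated as desaturases. The delta-12 desaturases NO14G02790 and NO11G02480 rose 2.91-fold and 2.53-fold, from 86.1 ± 19.7 to 264 ± 70.2 and from 80.8 ± 2.70 to 215 ± 12.6 FPKM (adjusted p = 0.0175 and 0.00139). Camera called the list as higher in low CO2 (adjusted p = 3.22e-05), but not with an estimated correlation (adjusted p = 0.315). Fry called it as well (adjusted p = 0.0158), but not with the replicate block (0.167). Without the 6, a choice made after seeing the data, the median of the other 23 was 0.61 and camera called the list (adjusted p = 4.62e-05), but again not with an estimated correlation (adjusted p = 0.438). Of the other lipid lists, none of 29 fatty acid synthesis genes, 27 genes of triacylglycerol assembly and lipid droplets, and 22 beta-oxidation genes passed. Their median log2 fold changes were -0.20, 0.23 and -0.24 (camera adjusted p = 0.177, 0.13 and 0.0766; fry adjusted p = 0.0295, 0.0555 and 0.0323; with an estimated correlation, camera gave 0.493, 0.493 and 0.438), and only triacylglycerol assembly had calls adjusted over the list alone, 3 higher. None of 14 storage glucan genes passed, also adjusted over the list alone (camera adjusted p = 0.394). The median of the desaturase list in high CO2 replicate 3 was -0.18 log2 from replicates 1 and 2, and that in low CO2 replicate 1 was -0.04 from replicates 2 and 3, a minus sign standing for lower.

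Among the photosynthesis lists, 1 gene passed. Their word patterns did not take in the ferredoxin NO09G00110, which fell from 1113 to 147 FPKM, so the lists do not cover every gene of electron transport. Of 13 photosystem and electron transport subunits, 1 of 3 genes described as iron-sulfur subunit 1 of the cytochrome b6-f complex (NO05G02070) fell from 284 ± 45.1 to 148 ± 13.6 FPKM (adjusted p = 0.0319), and 12 did not pass (1 lower adjusted over the list alone). The most abundant of these 3 genes, NO05G02030, was at 1423 ± 170 and 1469 ± 132 FPKM (log2 fold change -0.01, adjusted p = 0.979), and NO05G02050 at 45.9 ± 21.4 and 24.6 ± 15 FPKM (-0.94, adjusted p = 0.4). Counting between such copies is uncertain. None of 23 antenna proteins passed, with a median log2 fold change of -0.18, and 1 was higher adjusted over the list alone. Their median in high CO2 replicate 3 was 0.34 log2 above the other 2 high CO2 libraries. Without high CO2 replicate 2, camera called the antenna list as lower in low CO2 (adjusted p = 0.0404). With all libraries, the estimated correlation of 0.496 gave 0.78 and fry 0.349. Of 26 genes of tetrapyrrole and chlorophyll synthesis none passed (2 lower adjusted over the list alone), nor did any of 23 genes of carotenoid synthesis (3 higher adjusted over the list alone). Camera adjusted p-values were 0.216 for the subunits, 0.13 for the antenna, 0.765 for tetrapyrroles and 0.216 for carotenoids. Fry called the carotenoid list as higher in low CO2 (adjusted p = 0.0158), and the estimated correlation gave 0.532.

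**Figure D4:**
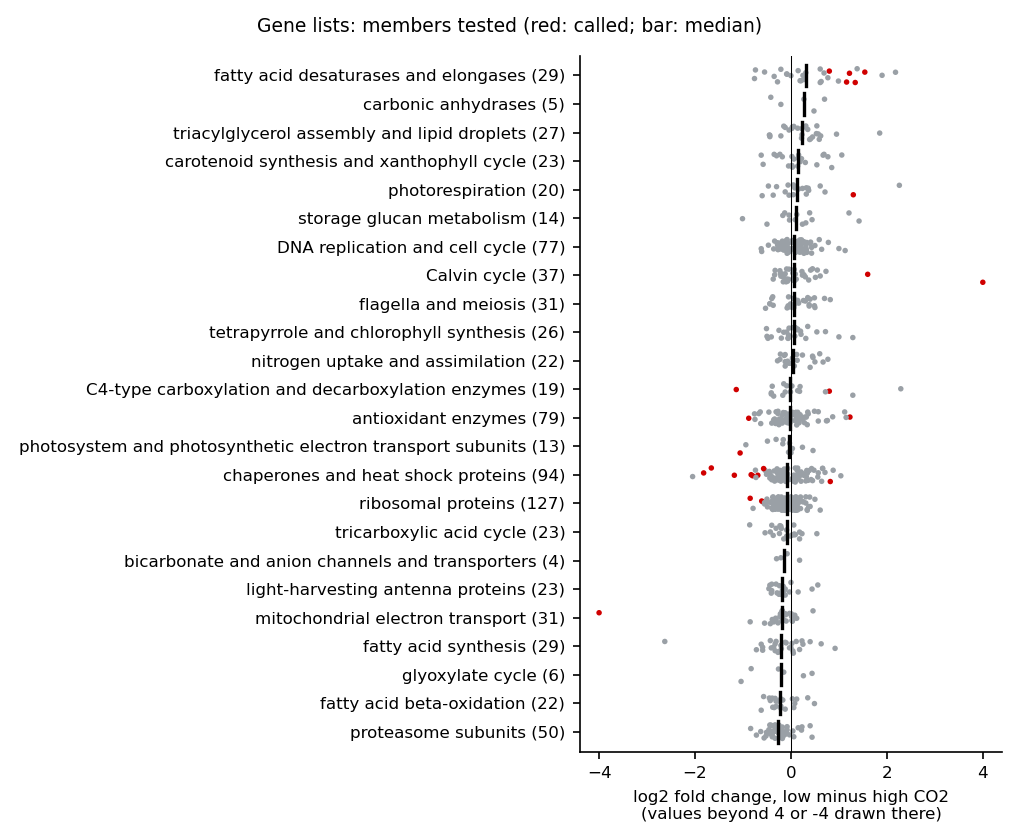
Log2 fold change (horizontal axis, low minus high CO2) of each tested member of 24 gene lists (1 line each, with the number of members tested), ordered by median, with values beyond 4 or -4 drawn there; members that passed the test are red and black bars are medians. The medians run from -0.28 for the 50 genes of the proteasome list to 0.31 for the 29 genes of the desaturase and elongase list, where 5 members are red.

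The list of proteasome subunits, parts of the protein-degrading complex, took in every gene with the word proteasome in its description. Of its 50 genes, none passed, also adjusted over the list alone, and their median log2 fold change was -0.28. Camera called the list as lower in low CO2 (adjusted p = 4.62e-05), but not with an estimated correlation (0.541), and fry gave 0.0894. At the preset correlation, camera still called the list without high CO2 replicate 3 (adjusted p = 0.00357) and without low CO2 replicate 1 (0.0226), but not without both (0.0851). In high CO2 replicate 3 the list's median was 0.28 log2 above the other 2 high CO2 libraries, and in low CO2 replicate 1 it was -0.02 from the other 2 low CO2 libraries. Of 31 genes of mitochondrial electron transport, the NADH dehydrogenase model at 0 (NO09G03180) fell and 30 did not pass (1 lower adjusted over the list alone), with a median of -0.18. That model is described after a bacterial gene and not as a subunit of the mitochondrial chain. Camera called this list (adjusted p = 0.0201), but not with an estimated correlation (adjusted p = 0.665). Without that 1 gene model the list's median stayed at -0.18, but the list did not pass (adjusted p = 0.148). Nor did it pass without high CO2 replicate 3 (0.08) or low CO2 replicate 2 (0.102). Its median was 0.23 and 0.24 log2 above the rest of the group in high CO2 replicate 3 and low CO2 replicate 1.

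Chaperones and heat shock proteins fell in 7 cases and rose in 1, of 94 tested (8 lower and 3 higher adjusted over the list alone). Those that fell are the heat shock protein 16 genes NO20G02130 and NO20G02150, the small heat shock proteins NO18G01280 and NO08G01140, a DnaJ homolog (NO12G00410) and the ClpB disaggregases NO20G02120 and NO16G01260, while other ClpB genes did not pass, among them NO06G02920 (log2 fold change -0.43, adjusted p = 0.203). The gene that rose, VTC4 (NO10G01110), is named a vacuolar transporter chaperone but belongs to the complex that makes polyphosphate. Camera gave an adjusted p of 0.157, and 0.438 with an estimated correlation, while fry gave 0.000206. Genes of this paragraph other than heat shock protein 16 were named after their values were seen.

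Of 127 ribosomal proteins, 60S protein L13 (NO20G00720) fell from 381 ± 27.6 to 294 ± 14.5 FPKM and 50S protein L34 (NO03G03180) from 93.8 ± 14.2 to 53.9 ± 4.98 FPKM (adjusted p = 0.0446 and 0.0456); 125 did not pass, and none passed adjusted over the list alone. The median of the ribosomal list in high CO2 replicate 3 and low CO2 replicate 1 was 0.37 and 0.21 log2 above the rest of the group. Camera gave an adjusted p of 0.13, and 0.00455 and 0.0404 without high CO2 replicates 1 and 2; without high CO2 replicate 3 its direction turned (0.90). With all libraries, the estimated correlation of 0.434 gave 0.84 and fry 0.561. Among 79 genes on the antioxidant list, the thioredoxin-domain protein PLP3B (NO06G01610) rose 2.35-fold, from 45.7 ± 4.73 to 112 ± 7.41 FPKM (adjusted p = 0.0101). It is on the list by the word thioredoxin, and its description does not name an antioxidant enzyme. The glutathione transferase-like GstA (NO04G02970) fell from 149 ± 7.53 to 84.0 ± 11.5 FPKM (adjusted p = 0.0414), and 77 did not pass (2 higher and 1 lower adjusted over the list alone). That list's median of -0.02 and mean of 0.01 differed in sign (camera adjusted p = 0.763). None of 22 genes of nitrogen uptake, 23 of the tricarboxylic acid cycle, 77 of DNA replication and cell cycle, and 31 of flagella and meiosis passed, over all genes or adjusted over the list alone. Their camera adjusted p-values were 0.251, 0.251, 0.763 and 0.617. The median of the DNA replication list in low CO2 replicate 1 was -0.40 log2 from replicates 2 and 3. The last of these lists stands for cell stages other than vegetative cells.

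The authors' deposited table of the same comparison listed 217 genes, 158 higher and 59 lower in low CO2, all with a log2 fold change of at least 1 either way. Of these, 211 were tested here and all 211 had the same sign. Pearson's r across these genes between the log2 fold changes in the authors' deposited table and those computed here was 0.999, from the same libraries and over genes that are not independent. Here 109 of the 217 passed, 71 higher and 38 lower, and they were the same 109 genes that passed with at least a 2-fold change. By DESeq2's Wald test with at least a 2-fold change, 217 genes passed, of which 209 were in the authors' deposited table. The other 102 genes tested had adjusted p-values here of up to 0.17, and 87 genes that passed here with smaller fold changes were not listed by the authors' deposited table.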

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

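The comparison of gene lengths was chosen after seeing the data. The mean transcript length that the authors' tables give per library was used by no comparison above, and it differed between groups for 1 of 3306 genes with several transcripts and at least 20 counts in every library. NO05G00750, a gene without a description, had a mean transcript length of 1620 ± 11.6 bases in high and 1831 ± 7.98 in low CO2 (SD, n = 3 per group; limma on log2 length, adjusted p = 0.0112), and its total also rose 2.03-fold (edgeR adjusted p = 0.00604). At an unadjusted p below 0.05 there were 351 genes. No explanation was tested for it. Groups of 3 libraries are too small for a test of single outlying libraries, and the design has no second contrast to compare with.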

How the results depend on the processing

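The fits without both libraries that stood apart and with the length trend removed, and the lists without genes of another function, were chosen after seeing the data. The 196 genes that passed kept their sign under every alternative in which they were tested, except 1 gene in limma on log2(FPKM + 1). No filter, a mean of at least 50 counts, RLE scaling and limma gave 193, 209, 196 and 182 genes, of which 192, 190, 191 and 147 were among the 196. DESeq2 gave 590, with 195 of the 196, and a 2-fold minimum left 109. Leaving out 1 library gave 18 to 1610 genes, the lowest without high CO2 replicate 2 and the highest without low CO2 replicate 1, where fewer samples were tested; the cause of the rise was not tested. Leaving out both high CO2 replicate 3 and low CO2 replicate 1 gave 3402 genes (193 of the 196), and removing the length trend gave 217 (169 of the 196). The labels tie no replicate number across groups. Deviations of same-numbered libraries from their group means correlated at -0.356, 0.083 and -0.433. Such deviations sum to 0 within a group and libraries stood apart in both groups, so these values cannot decide on pairing. With the replicate block, 21 genes passed, all among the 196, and 9 of the 27 named genes were among them. Of the 27 named genes, none changed sign, and 27, 24, 26, 27 and 24 passed with no filter, 50 counts (24 tested), RLE, DESeq2 and limma.

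Camera called 3 lists, 0 with an estimated correlation, and 1 without both libraries (the desaturases). Leaving out 1 library gave 3 to 5 lists. Fry called 6 lists, and 0 with the replicate block (0.0632 for the chaperones), under which camera called 4, the Calvin cycle list among them (adjusted p = 0.00992). The adjusted p of that list ran from 0.00992 to 0.438 over the alternatives, all of which kept the phosphoribulokinase model at 0. The desaturase list was called under 14 of 16 alternatives, the proteasome list under 12 and mitochondrial electron transport under 9. The cause of these differences was not tested. The 109 genes shared with the authors' table were the same number with and without a 2-fold minimum. Alternatives for an FPKM-only design were not run.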

Other observations

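The genes and pathways of the first 2 paragraphs, and the tests of phosphate genes, of gene models at 0 and of other splits of the libraries, and those of low CO2 replicate 1 beside held-out high CO2 libraries and at gene models at 0, were chosen after the results were seen; the other tests of libraries that stood apart and of gene length in lists were set before their own results were seen, though after the pattern. Beyond the genes named by the rule, the called genes held a plasma membrane-type proton ATPase pair, NO12G00380 and NO12G00390. They rose 6.88-fold and 5.09-fold in low CO2 (edgeR adjusted p = 0.0142 and 0.032), while the neighbouring NO12G00370, of like description, was at 504 ± 14.2 and 560.3 ± 195 FPKM (SD, n = 3; edgeR adjusted p = 0.848). Counts of such neighbours are uncertain where they share reads. Formate-tetrahydrofolate ligase, a folate enzyme of one-carbon metabolism, was called at NO24G01020 (2.60-fold higher, adjusted p = 0.0103) and NO24G01030 (6.54-fold higher, adjusted p = 0.0205). Their locus numbers are consecutive, so the same uncertainty of counts applies. With serine hydroxymethyltransferase 2, these ligase genes, counted separately, were the 3 of 16 genes called in the pathway of the one carbon pool by folate. It was the highest of 106 pathways tested among genes that rose, and did not pass (one-sided Fisher's exact test by the hypergeometric tail, p = 0.00116, adjusted p = 0.0719). Among genes that fell, ubiquinone and other terpenoid-quinone biosynthesis was highest, with 3 of 17 genes (the same exact test, p = 0.000924, adjusted p = 0.098).

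Of 27 genes with descriptions of phosphate supply, 5 were called, all higher in low CO2. The phosphate permease PHO89 (NO24G00190) was 3.03-fold higher in low CO2 (adjusted p = 0.00104), a phosphate transporter annotated as 1-2 (NO16G02030) 4.30-fold (adjusted p = 0.0407), purple acid phosphatase 4 (NO12G01720) 1.77-fold, the sulfolipid synthesis enzyme SQD2 (NO07G01720) 1.87-fold and the polyphosphate synthesis gene VTC4 (NO10G01110) 1.76-fold. A hypothesis is that the whole group rises, not only those 5. The other 22 were not called, and 15 of these 22 were above 0. Their median log2 fold change of 0.24 lay above 99.8% of 10000 random lists of genes not called, matched on expression (95% of which had medians of -0.19 to 0.15), which is consistent with the hypothesis but was found and tested on the same libraries. Random lists of single genes do not allow for genes that move together, and camera with an estimated correlation gave an unadjusted p of 0.123. The median of the 22 ranged from 0.15 without high CO2 replicate 3 to 0.32 without high CO2 replicate 1. Medium phosphate was not measured in the data used here.

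The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 196 genes and the highest of the others 0, with 1 split at the real count or above. For gene lists, the real split called 3 and the highest other split 4, with 7 splits, the real one among them, at 3 or more. Wrong groupings of the libraries thus called as many lists as the real one, so the number of lists called gives no evidence of a CO2 difference. Gene models at 0 in 1 group and at 10 counts or more in every library of the other numbered 8 in the real split and at most 3 in the others, again with 1 split at that value.

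Those 8 gene models at 0 in a whole group were set against sharing of reads with a neighbour. A consecutive locus number with the same description was present for 4 of the 8 (50%), against 499 of 9244 genes tested (5.4%; Fisher's exact test, two-sided, p = 0.000493). For those 4, an assignment of shared reads that differs between groups is a candidate explanation. Where they were above 0, the models took 9.06% (phosphoribulokinase), 8.01% (pyruvate kinase), 12% (TATDN1) and 6.64% (polyprenyltransferase) of the summed pair. A plain exchange of reads lowers the neighbour where the model is above 0. The longer phosphoribulokinase (log2 fold change -0.21) and polyprenyltransferase (0.27) lay in that direction, while the longer pyruvate kinase and TATDN1 genes (0.42 and 0.38) lay in the other, none of them called. Sharing of reads stays open for the other 4, most of which have no description to compare. A CO2 response of the models themselves, such as a transcript that starts elsewhere, stays open and was untested, since neither reads nor positions were used.

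High CO2 replicate 3 and low CO2 replicate 1 stood apart from their groups. The tables argue against depth: after all libraries were thinned to the lowest total, high CO2 replicates 1 and 3 differed over 2-fold at 828 genes (189 for replicates 1 and 2), and low CO2 replicates 1 and 2 at 1162 (111 for replicates 2 and 3). They argue as well against gene length as the whole cause, since 802 and 1077 genes remained over 2-fold once the trend was removed. Exchange of labels was tested on genes called without the library, on a scale of 0 at the high and 1 at the low CO2 mean: high CO2 replicate 3 had a median position of -0.02 over 68 genes, which argues against a low CO2 culture, while low CO2 replicate 1 lay at 0.31, between the bounds set beforehand (39.8% of genes above 0.5 and 6.38% below -0.5). For high CO2 replicate 3 these were all genes called, and for low CO2 replicate 1 the 517 called with at least a 2-fold change that were also tested with all libraries. Over all genes called without each, the 3 high CO2 libraries had at most 2.86% above 0.5 and medians of -0.02 to 0.03, and low CO2 replicates 2 and 3 had 97.9% and 98.0% above 0.5 and medians of 1.00 and 0.94. Held-out high CO2 libraries, over genes called with at least a 2-fold change from the other 2 high CO2 libraries and low CO2 replicates 2 and 3, lay above 0.5 at 15.4%, 3.6% and 10.4% of genes (replicates 1, 2 and 3), and low CO2 replicate 1 at 37.8%, 45.6% and 37.9%, at least 2.45 times as many, though its median of 0.34 was under the upper quartile of replicate 1 (0.38). A set of 23 genes split the 3 high CO2 libraries from low CO2 replicates 2 and 3. These were at 0 on 1 side and at 10 counts or more on the other. At these, low CO2 replicate 1 was on the low CO2 side at 8 (34.8%) and on the high CO2 side at 12. Held-out high CO2 libraries had their own sets of 32, 29 and 25 genes, chosen with only the other 2 high CO2 libraries and low CO2 replicates 2 and 3. They were on the low CO2 side at 18.8%, 17.2% and 8.0%, and on the high CO2 side at 23 genes each. Low CO2 replicate 1 was thus on the low CO2 side more often than held-out high CO2 libraries. Its r and its place on component 1 were nearer high CO2 replicates 1 and 2 than low CO2 replicates 2 and 3. The tests of low CO2 replicate 1 fell between the bounds set for each, so a mislabelled or mixed culture cannot be told apart from a weaker or other response. No biological explanation for single reactors was tested.

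The lower proteasome and mitochondrial lists were set against the gene length trend. With all libraries, both were called by camera at the preset correlation, and neither with an estimated correlation (adjusted p = 0.541 and 0.665) or by fry (0.0894 and 0.216), so the tests concern that call and the medians. With the trend removed, the proteasome median went from -0.28 (quartiles -0.41 and -0.12) to -0.23 (quartiles -0.39 and -0.11). The median of genes off that list was 0.02 both times. A median that stayed lower argues against the trend as the whole cause of the lower median. Camera at the preset correlation still called the list (adjusted p = 0.000238). Wrong groupings of the libraries called as many lists as the real one, so such calls cannot decide on a cause. The mitochondrial median went from -0.18 (quartiles -0.32 and 0.01) to -0.10 (quartiles -0.20 and 0.03), while the median of other genes was 0.02 both times, and the call ended (adjusted p = 0.162). The call ended as well without NO09G03180 (0.148), where the median stayed at -0.18. Why it ended was not tested, so the length trend and a CO2 response cannot be told apart there. The proteasome list was called without high CO2 replicate 3 (0.00357) and without low CO2 replicate 1 (0.0226), but not without both (0.0851). The call thus did not need either library alone, but it cannot decide whether these libraries caused the lower median. A response to CO2 stays open and was untested.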
